A study of Mus musculus with 8 samples.

How the data were processed

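Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open chromatin, in conventional dendritic cells of mouse spleen. Spleen cells were enriched for dendritic cells and sorted as lineage-negative CD11c+MHCII+CD64- cells. Type 1 cells (cDC1) were XCR1+CD11b- and type 2 cells (cDC2) were XCR1-CD11b+. The mice carried a floxed Hdac1 gene without Cre (called WT here) or with Mx1-Cre (called KO), and all had received poly I:C, which switches on Mx1-Cre, 2 weeks before the sort. The 8 libraries form 4 groups of 2, taken from the sample titles. The labels do not state that the libraries of a group come from separate animals, so the p-values measure only the spread between these libraries.

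For each library the authors deposited a list of summits, the point of highest signal within each called peak, with 1 summit per peak. Per the labels, the authors used Bowtie2, SAMtools, MACS2 and MultiQC with the GRCm38 (mm10) mouse genome. Versions, filters and peak calling settings are not stated. The score in the deposited lists is a negative log10 p-type value given to each peak within its own library. It was taken to be the negative log10 of the MACS2 q value, because its lowest value lay between 1.3 and 1.36 in every library. Such scores rise with sequencing depth, so in the main results they served only to rank summits within a library. Cuts at a fixed score were used only as alternatives and follow depth. The lists hold no read counts. The depth of each library is therefore unknown, and no counting interval or detection limit could be given. A gene at 0 summits had no called peak assigned to it, which does not show closed chromatin.

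Lists of equal length were made by keeping the 61737 summits with the highest score in each library, the length of the shortest list. Each summit was given to the nearest of 21887 protein-coding genes of the GRCm38.p6 annotation, at most 50 kb from the gene. The annotation gave gene spans without strand or exons. The planned distance to the transcription start was therefore replaced by the distance to the gene span, and summits near promoters by summits within 1 kb of either gene end. A split into exons and introns could not be made. A genome sequence was not used here, so the planned motif search was not run. Sites were made by chaining summits of any library that lay within 250 bp of each other. A site counted as found in a subset or genotype only when every library of that side and no library of the other had a summit in it. Overlap between libraries was the Jaccard index of their sites, the number of shared sites over the number found in either.

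Summits per gene were analysed as log2(summits + 1) for the 14068 genes with a mean of at least 1 summit over the 8 libraries, with limma 3.58.1 in R 4.3.3. The model had a mean for each of the 4 groups and 7 contrasts. These were cDC2 minus cDC1 over both genotypes, in WT and in KO, KO minus WT in cDC1, in cDC2 and over both, and the difference between the genotype effects of the subsets. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05. Log2 differences are differences between group means on this scale, where a change in the number of called peaks is counted and not a change in reads.

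The fit as planned was tested on simulated data and failed. In 5 simulated sets without any change it called 106 to 221 genes per contrast, because libraries with identical small counts gave variances near 0. With changes added to 200 genes it recovered 6 of 100 at 2-fold and 29 of 100 at 4-fold, and called 175 unchanged genes. The fit reported here adds to each variance the rounding variance of a whole number, 0.0833 squared summits. It called 0 to 3 genes per contrast in the sets without change, recovered 43 of 100 at 2-fold and 94 of 100 at 4-fold, and called 6 unchanged genes. It was chosen after the data had been seen, from 6 variance treatments tried on both the data and the simulated sets. In the simulated sets each site had a probability of a summit based on its frequency over the 8 libraries. Libraries were drawn independently from it, without differences between animals, batches or depth. The counts in sets without change therefore do not give the error rate in the real libraries. The counts of the planned fit stand beside those reported.

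The other choices were made before the data were examined, among them 18 gene lists and the rule for named genes. The lists were cDC1 identity, cDC2 identity, pan-cDC and MHC class II, DC transcription factors, plasmacytoid DC, monocyte and macrophage, T cell, B cell, NK cell, granulocyte, erythroid and megakaryocyte, interferon-stimulated, DC maturation and cytokines, MHC class I and cross-presentation, histone deacetylases and HDAC1 complexes, cell cycle and growth arrest, toll-like and innate sensing, and housekeeping. They were tested with limma camera at a preset correlation of 0.01, again with an estimated correlation and with fry, and against 10000 random lists. Named genes were the 12 largest changes in each direction among called genes whose libraries did not overlap between the sides, 16 genes fixed by name, and up to 4 members of each list with the smallest p. Where fewer than 5 genes passed in a direction, the rule added the 5 with the smallest p. Gcsam, Ccl17, Pdzph1 and, over both subsets, Epha3, Krt8 and Lypd6 fall outside the rule and were chosen after their values were seen. Named sites were the 10 of each class with the best median rank of score.

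Summits per library and the shares of summits near gene ends, inside genes and outside them were compared with 2-sided exact permutation tests, 4 libraries against 4, whose smallest p is 0.0286. With 2 libraries against 2 no p under 0.05 can be reached, so genotype effects on single values within a subset were not tested. Peak names in the deposited lists carry a tag shared by the cDC1 and the cDC2 library of the same number and genotype. The labels do not state that such libraries come from the same animal. If they do, genotype effects over both subsets rest on 2 animals per genotype. Correlations across genes of the deviations of equal-numbered libraries lay between 0.00206 and 0.0362, so a block for the number was run only as an alternative. Other alternatives were all deposited summits, the 30868 best summits of each list, a gene span with 5 kb on both sides, a limit of 10 kb to a gene end, a pseudocount of 0.5, no filter on low genes or a mean of at least 3 summits, autosomes, trend and robust variance, the groups of a contrast alone, windows of 500 bp and 2 kb, site distances of 100 and 500 bp, and leaving out each library. Where this left a group with 1 library, that library was assumed to vary like those of the other groups. Added after the data were seen were the variance treatments, leaving out both libraries of KO number 2, a score of at least 10 for sites, and counting sites with no summit of the other side within 1 kb. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used.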

Results

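Open chromatin was mapped in cDC1 and cDC2 of mouse spleen, with or without Mx1-Cre deletion of Hdac1, a gene for a histone deacetylase that removes acetyl groups from histones. There were 2 libraries each of WT cDC1, KO cDC1, WT cDC2 and KO cDC2. The read depth of the libraries is unknown. The deposited lists held 76022 and 77585 summits in WT cDC1, 74963 and 96031 in KO cDC1, 66609 and 61737 in WT cDC2, and 69025 and 78296 in KO cDC2. A list had a mean of 81150 ± 9979 summits in cDC1 and 68917 ± 6949 in cDC2 (SD, n = 4), which did not pass the 2-sided exact permutation test (p = 0.114). With libraries paired by number and genotype, the cDC2 list was shorter in 4 of 4 pairs, at the smallest possible sign-flip p of 0.125. Without replicate 2 of KO cDC2 the difference of -15360 passed. All other values come from lists of 61737 summits per library. They are numbers of called peaks, and the log2 differences are on the scale of summits plus 1.

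**Figure D1:**
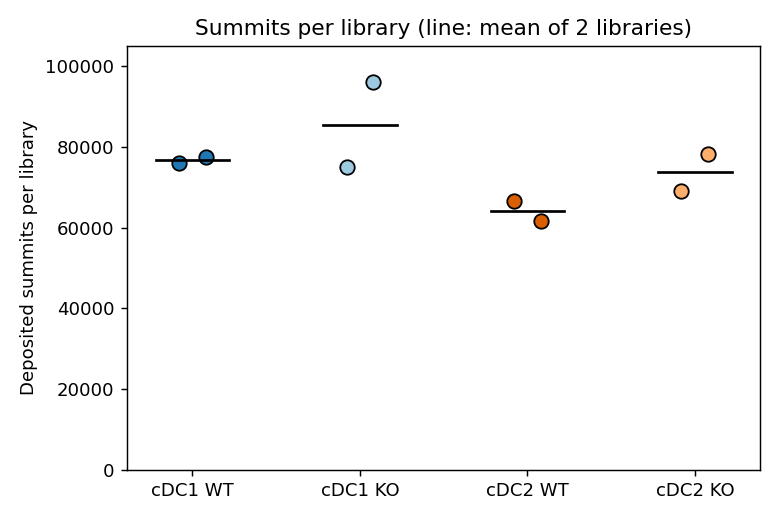
Number of deposited summits per library (vertical axis) for the 4 groups (horizontal axis). Points are libraries and lines are means of 2 libraries. Replicate 2 of KO cDC1 had 96031 summits and the other 3 cDC1 libraries had between 74963 and 77585.

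The first comparison asks how the open chromatin of cDC2 differs from that of cDC1 over both genotypes. The 2 subsets differed at 1457 of 14068 genes, of which 661 had more summits in cDC2 and 796 fewer. As a set, genes of cDC1 identity fell in cDC2. Cd8a (chromosome 6, 71373427 to 71379171), which encodes the CD8 alpha chain carried by splenic cDC1, had 6 ± 0.816 summits in cDC1 and 0.25 ± 0.5 in cDC2 (SD, n = 4, adjusted p = 4.42e-06). Irf8 (chromosome 8, 120736358 to 120756694), the transcription factor required for cDC1, had 14.8 ± 0.957 summits in cDC1 and 9 ± 1.83 in cDC2, a log2 difference of -0.67 (SE 0.172, adjusted p = 0.0222).

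Of the 23 tested genes of the cDC1 identity list 5 fell in cDC2, 0 rose and 18 did not pass. Adjusted over the list alone, 6 were lower and 1 higher. The list as a set was lower in cDC2 (median log2 difference -0.26, adjusted p = 0.0021). Its adjusted p = 0.0379 with an estimated correlation. Beside Cd8a and Irf8, the members that fell were Plpp1, Cadm1 and Gcsam. Plpp1 differed by -1.15 (SE 0.187, adjusted p = 0.00125), and Cadm1, an adhesion molecule of cDC1, by -0.85 (SE 0.173, adjusted p = 0.00566). Gcsam differed by -1.14 (SE 0.308, adjusted p = 0.0283), and did not pass with a pseudocount of 0.5 (adjusted p = 0.114), without the filter on low genes (0.0948) or in the fit as planned (0.234). Batf3, a transcription factor of cDC1, had a log2 difference of 0.19 (adjusted p = 0.595) and Clec9a, a receptor for dead cells on cDC1, 0.44 (adjusted p = 0.169). Nfil3, another list member, was higher in cDC2 by 0.597 and did not pass. It passed with trend and robust variance (adjusted p = 0.00145), with the block (0.0449) and among genes with a mean of at least 3 summits (0.0283). With summits limited to 10 kb from a gene end Cadm1 turned direction (0.189, adjusted p = 0.819) and Plpp1 did not pass (-0.534, adjusted p = 0.113). Plpp1 also did not pass with the gene span with 5 kb on both sides (-0.374, adjusted p = 0.212). Irf8 kept its direction but did not pass without replicate 1 of WT cDC1 (-0.627), replicate 2 of KO cDC1 (-0.648), replicate 2 of WT cDC2 (-0.629) or replicate 2 of KO cDC2 (-0.64). Xcr1, the receptor used to sort cDC1, was not tested, because the 1 to 3 deposited summits per library at its locus, in both subsets, were assigned to the neighbouring gene Fyco1.

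Of the 22 tested genes of the cDC2 identity list 2 rose in cDC2, 0 fell and 20 did not pass. Adjusted over the list alone, 5 were higher and 0 lower. The set was higher in cDC2 (median log2 difference 0.214, adjusted p = 0.0218, and adjusted p = 9.22e-06 with an estimated correlation). That correlation was negative (-0.0267), which makes p smaller, so the second value adds no support. The risers were Clec4a4, a C-type lectin receptor, with 0.75 ± 0.5 summits in cDC1 and 2.5 ± 0.577 in cDC2 (SD, n = 4, adjusted p = 0.0063), and Dtx1, a Notch pathway gene, with a log2 difference of 0.85 (SE 0.196, adjusted p = 0.0129). Neither passed in the fit as planned (adjusted p = 0.0746 and adjusted p = 0.0668). Clec4a4 did not pass with all deposited summits (0.145), nor Dtx1 with the limit of 10 kb (0.107) or without both libraries of KO number 2 (0.0744). The set did not pass with all deposited summits (adjusted p = 0.268), without replicate 1 of WT cDC1 (adjusted p = 0.0521) or without replicate 1 of KO cDC1 (adjusted p = 0.0545). Sirpa, a surface receptor of cDC2, differed by 0.57 (adjusted p = 0.0617) and Zeb2, a transcription factor of cDC2, by 0.53 (adjusted p = 0.0756), and neither passed. Both passed among genes with a mean of at least 3 summits (adjusted p = 0.0198 and adjusted p = 0.0252), and with trend and robust variance (0.0107 and 0.000276), rounding and trend (0.00898 and 0.00021) or the loess average (0.0286 and 0.0404). Sirpa also passed without replicate 2 of WT cDC2 (0.0358). Irf4, another transcription factor of cDC2, differed by 0.27 and Itgam, which encodes the CD11b used in the sort, by -0.08, again without passing.

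Innate sensors moved both ways. Among toll-like and innate sensing genes 2 of 21 rose in cDC2 and 1 fell. The endosomal RNA sensors Tlr7 and Tlr8 rose by 0.94 (SE 0.265, adjusted p = 0.0366) and 0.76 (SE 0.174, adjusted p = 0.012). Tlr12, a sensor of parasite profilin, fell by 1.04 (SE 0.265, adjusted p = 0.0221). Without replicate 1 of KO cDC1, Tlr7 differed by 0.541 and no longer passed. With the limit of 10 kb neither Tlr7 (0.411) nor Tlr8 (0.415) passed, and Tlr8 differed by 0.25 among the 30868 best summits (adjusted p = 0.571). Tlr12 differed by -0.458 with the gene span with 5 kb on both sides (adjusted p = 0.289). In the fit as planned Tlr7 (0.218) and Tlr12 (0.177) did not pass. Among DC maturation and cytokine genes Il6, Cd200, Il10 and Ccl17 were lower in cDC2 and Tnf was higher, out of 26. Of these Il6 differed by -0.78 (SE 0.182) and Tnf by 0.75 (SE 0.196). Tnf and Il10 turned direction among the 30868 best summits of each list, without passing there. Il6 differed by -0.354 there and did not pass either (adjusted p = 0.321).

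Among interferon-stimulated genes Oas1a and Gbp2 rose, Trim30a fell and 14 of 17 did not pass. Oas1a differed by 1.25 (SE 0.221, adjusted p = 0.00204) and Trim30a by -0.92 (SE 0.174, adjusted p = 0.00359). With all deposited summits Trim30a differed by -0.525 and did not pass (adjusted p = 0.0903). Of the DC transcription factors Irf8 and Stat3 fell, 2 of 28. Of the histone deacetylases and HDAC1 complexes the corepressor genes Ncor1 and Sin3a fell, 2 of 30, and of the cell cycle genes Cdk1 fell, 1 of 23. Cdk1 differed by 0 among the 30868 best summits. Sdha fell among 13 housekeeping genes, but differed by -0.146 among the 30868 best summits (adjusted p = 0.843). Adjusted over the list alone, neither corepressor nor Sdha passed, and 1 of the 28 transcription factors did. No member passed among 18 genes of MHC class I and cross-presentation, 14 of the pan-cDC and MHC class II list, or 11 of NK cells.

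Markers of other cell types also moved both ways. The plasmacytoid DC genes Pacsin1 and Cox6a2 fell in cDC2, 2 of 15. Among T cell genes Tcf7 rose by 0.83 (SE 0.19, adjusted p = 0.0117) and Cd8b1, the partner chain of Cd8a, fell by 1.06 (SE 0.242, adjusted p = 0.012), out of 15. Tcf7 differed by 0.25 with the limit of 10 kb (adjusted p = 0.627) and did not pass without both libraries of KO number 2 (0.0739). Cd8b1 differed by -0.292 among the 30868 best summits (adjusted p = 0.444). The neutrophil collagenase gene Mmp8 rose, 1 of 7 granulocyte genes. Vcam1 (1 of 18 monocyte and macrophage genes), Ebf1 (1 of 9 B cell genes) and Itga2b (1 of 7 erythroid and megakaryocyte genes) fell. Beside Irf8 and Tlr7, 12 of the list members called here lost the call when 1 library was left out. Without replicate 2 of KO cDC2 Stat3 (-0.535), Sin3a (-0.618), Sdha (-0.496), Ebf1 (-0.594), Itga2b (-0.656), Vcam1 (-0.566), Gbp2 (0.604), Tnf (0.646), Il10 (-0.639) and Ccl17 (-0.623) did not pass, and without replicate 1 of KO cDC1 Ncor1 (-0.639) and Cd200 (-0.623) did not. Over all alternatives, 24 of the 53 named genes called here kept direction and call wherever they were tested, Cd8a, Pacsin1 and Mmp8 among them. The other 29 lost the call in 1 to 15 alternatives, with Sin3a (15), Stat3 (14) and Sdha (14) losing it most often. Some also failed without other libraries, and Ebf1 turned direction with summits limited to 10 kb from a gene end. As sets, the 16 lists other than cDC1 and cDC2 identity did not pass (adjusted p between 0.735 and 0.975). With fry the list of histone deacetylases and HDAC1 complexes was lower in cDC2 (adjusted p = 0.0102) and the cell cycle list higher (0.000185).

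**Figure D2:**
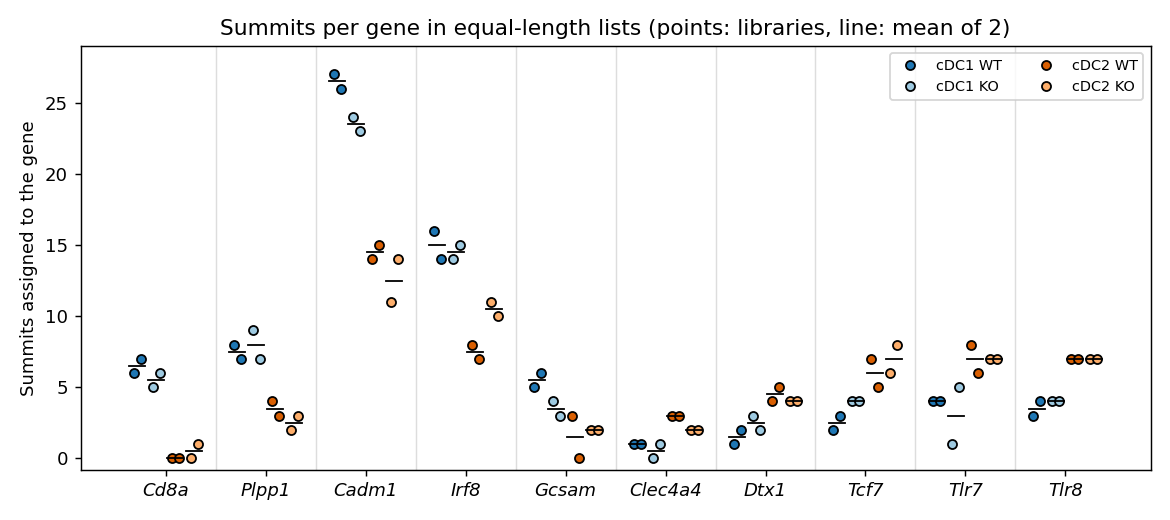
Summits assigned to 10 named genes (vertical axis) in the equal-length lists, by group. Points are libraries and lines are means of 2 libraries. Every cDC1 library had 5 to 7 summits at Cd8a and every cDC2 library had 0 or 1.

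Most of the largest changes were at genes outside the lists. Scn11a, which encodes a voltage-gated sodium channel, had 0.25 ± 0.5 summits in cDC1 and 9 ± 0.816 in cDC2 (SD, n = 4, adjusted p = 1.21e-06). Tmem132c had 1.75 ± 0.5 and 12.5 ± 1 (adjusted p = 3.26e-06), and Cd2, an adhesion receptor, 0.75 ± 0.957 and 5.25 ± 1.26 (adjusted p = 3.34e-05). Others of this kind were 4930503B20Rik, Pou3f3, C1qtnf3, Kctd12b, Ryr3, Scn3a, Nr2f2 and Nsg2. In the other direction Chst9, a sulfotransferase gene, had 7 ± 2.16 summits in cDC1 and was listed at 0 in every cDC2 library (adjusted p = 1.21e-06). Pcsk5, which encodes a proprotein convertase, had 4 ± 0.816 in cDC1 and was also listed at 0 in cDC2 (adjusted p = 3.26e-06). Dcdc5, Zkscan2, Ankrd31, Luzp2, Sh3gl3, Cnnm1, Mrgprd, Rtl4 and Tpte followed.

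The variance treatment behind these counts was chosen after the data were seen, and the fit as planned called 1269 genes, of which 744 were among the 1457.

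Single sites separated the subsets as well. Of 112443 sites, 4865 had a summit in every cDC1 library and in no cDC2 library, and 2719 the reverse. Of these, 4355 and 2261 had no summit of the other subset within 1 kb. The cDC1-only sites included 9 at Dlg2, 9 at P3h2, 8 at Plcb4, 5 at Cadm1, 4 at Cd8a, 3 at Flt3, 3 at Il12b and 2 at Irf8. The cDC2-only sites included 7 at Tmem132c, 6 at Scn11a, 6 at Dpp10, 2 at Dtx1, 2 at Tlr8 and 1 at Sirpa. Identity genes of the opposite subset also held such sites. Of the cDC2 list, Notch2 had 2 cDC1-only sites, and Itgam, Klf4, Rbpj, Zeb2 and Cx3cr1 had 1 each. Of the cDC1 list, Nfil3 had 2 cDC2-only sites, and Btla, Cd24a, Ly75, Rab7b and Wdfy4 had 1 each. Notch2, Klf4, Zeb2, Cx3cr1, Cd24a and Wdfy4 had sites of both kinds. Il12a had 3 cDC2-only sites. A highly ranked cDC1-only site, without a cDC2 summit within 1 kb, lay at Kcnh8 (chromosome 17, 52626195 to 52626250), and a cDC2-only site at Dpp10 (chromosome 1, 123752082 to 123752154). At Tom1 and Insig1 the subset-only sites of cDC1 and cDC2 lay 396 and 669 bp apart.

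Libraries of the same group shared more sites than libraries of the other subset. The mean Jaccard index was 0.673 ± 0.0179 for the 4 pairs within a group, 0.659 ± 0.0146 for the 8 pairs of the same subset and other genotype, and 0.518 ± 0.0111 for the 16 pairs across subsets (SD over pairs, which share libraries). Summits within 1 kb of a gene end made up 20.1% ± 0.357 of the list in cDC1 and 21.0% ± 0.261 in cDC2 (SD, n = 4, exact permutation p = 0.0286, adjusted p = 0.0429 over 3 shares). Summits inside genes made up 44.4% ± 0.321 and 43.4% ± 0.344 (exact permutation p = 0.0286, adjusted p = 0.0429), and summits outside genes 35.5% ± 0.249 and 35.6% ± 0.298 (exact permutation p = 0.629). With libraries paired by number and genotype, the near-end share was higher and the inside share lower in cDC2 in 4 of 4 pairs, at the smallest possible p of 0.125. Among the 30868 best summits the near-end and inside shares no longer passed (differences 0.232 and -0.743), nor did they with a window of 500 bp (0.468 and -0.646). The near-end difference also failed to pass with all deposited summits (2.45, exact permutation p = 0.0571), and without replicate 2 of KO cDC1 (0.781), replicate 1 or 2 of WT cDC2 (0.882 and 0.785), or replicate 1 or 2 of KO cDC2 (0.865 and 0.996). The inside difference failed without replicate 1 or 2 of WT cDC1 (-0.86 and -0.917), replicate 2 of WT cDC2 (-0.831) or replicate 1 of KO cDC2 (-0.941).

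**Figure D3:**
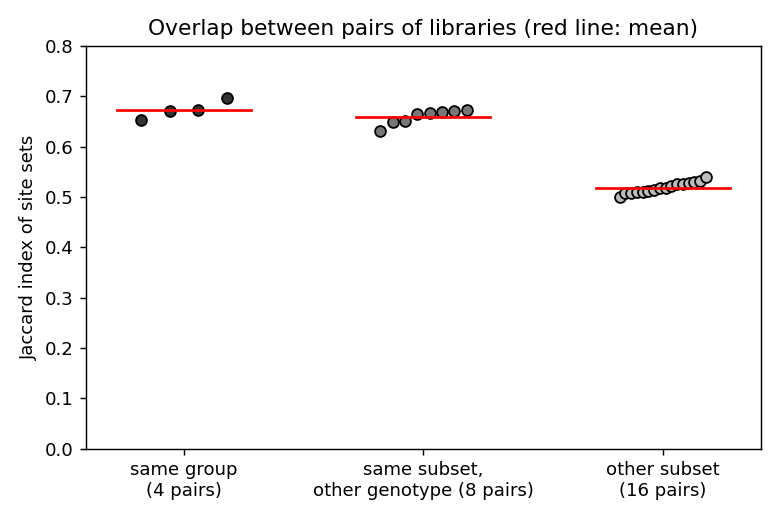
Jaccard index of site sets (vertical axis) for pairs of libraries of the same group, of the same subset and other genotype, and of different subsets (horizontal axis). Points are pairs and red lines are means. The 16 pairs across subsets lie between 0.499 and 0.54, below the 12 pairs within a subset.

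The next comparison takes the subset difference within each genotype, to see whether cDC1 and cDC2 stay distinct in the KO genotype. In WT 522 genes separated the subsets, 245 higher and 277 lower in cDC2. In KO 246 genes did, 99 higher and 147 lower. Of the WT calls, 470 of 522 had the same sign in KO, and of the KO calls 242 of 246 had the same sign in WT. There were 143 genes called in both, 59 higher and 84 lower, where independent lists would share 1.72 and 2.89, and 0 were called in opposite directions. Both sets of calls share a variance estimate.

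Genes with the largest subset differences were called in both genotypes. Cd8a had 6 and 7 summits in WT cDC1, 5 and 6 in KO cDC1, 0 and 0 in WT cDC2 and 0 and 1 in KO cDC2. Scn11a, Tmem132c, Chst9, Dcdc5, Pcsk5 and Ankrd31 were also among the changes of largest size in both genotypes. Not every cDC1 gene called over both genotypes was called within each. Of the 23 tested cDC1 identity genes 3 passed in WT and 2 in KO. Irf8 differed by -0.91 in WT, where it passed, and by -0.43 in KO, where it did not. In WT it did not pass with a pseudocount of 0.5 (adjusted p = 0.099), without the low filter (0.124) or with the groups of the contrast alone (0.0583). Cadm1 differed by -0.83 in WT and -0.87 in KO and passed in neither. The cDC1 identity list was lower in cDC2 in WT (adjusted p = 0.00637) and in KO (adjusted p = 0.0128). With an estimated correlation neither passed (adjusted p = 0.0532 in WT and adjusted p = 0.107 in KO). With all deposited summits the KO value did not pass (adjusted p = 0.0999). Nor did the WT value without replicate 2 of WT cDC1 (0.104) or WT cDC2 (0.151), or the KO value without replicate 1 of KO cDC1 (0.0548) or KO cDC2 (0.121). The cDC2 identity list was higher in KO (adjusted p = 0.0346) and did not pass in WT (adjusted p = 0.0823). With the block (adjusted p = 0.0501) or all deposited summits (0.311) it did not pass in KO either. With an estimated correlation, again negative (-0.0267), the list passed in KO and in WT (adjusted p = 3.07e-05 and adjusted p = 0.000287). The KO value did not pass without replicate 1 or 2 of WT cDC1 (0.0516 and 0.0533), replicate 1 of KO cDC1 (0.16) or replicate 1 of KO cDC2 (0.121).

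The difference between the genotypes was tested directly. With limma, 0 genes had a genotype effect that differed between cDC1 and cDC2, with 537 genes at an unadjusted p under 0.05. The fit as planned called 299. In the reported fit no single gene was thus shown to separate the subsets less in KO. The block and trend and robust variance each called 38 genes, the 30868 best summits 35 and the 10 kb limit 12. All deposited summits, the 5 kb span, a pseudocount of 0.5, no low filter, a mean of 3 summits and autosomes called 0. In simulated sets without change, run for other contrasts, the block called 21 to 65 genes and trend and robust variance 19 to 36. The fit as planned called 639 genes in WT and 505 in KO, and fits to the groups of the contrast alone called 817 and 682. With any 1 WT library left out 546 to 633 genes were called in WT and 679 to 694 in KO, and with any 1 KO library left out 829 to 856 and 304 to 363. The genotype that lost a library had fewer genes each time, so these fits do not compare the genotypes on equal terms. The mean Jaccard index between cDC1 and cDC2 was 0.512 ± 0.0119 in WT and 0.532 ± 0.00613 in KO (SD over 4 pairs that share libraries).

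The comparison of KO with WT asks which chromatin differences go with the KO genotype, floxed Hdac1 with Mx1-Cre, in each subset. In cDC1 7 genes passed, 6 with more summits in KO and 1 with fewer. Epha3 (chromosome 16, 63543532 to 63864175), which encodes an ephrin receptor, was listed at 0 in both WT cDC1 libraries and had 3 and 4 summits in KO (adjusted p = 0.00327). Cd96, a receptor that binds nectin family ligands, and Lypd6 were listed at 0 in WT and had 3 and 3 summits in KO (adjusted p = 0.0324 and adjusted p = 0.0255). Tom1l1, Flrt1 and Esrrg also rose, from 0 to 2 or 3 summits. Gak, which encodes a kinase of clathrin uncoating, fell from 2 and 2 summits to 0 in both KO libraries (adjusted p = 0.0324). With all deposited summits Cd96 (0.597), Lypd6 (1.2), Flrt1 (1.04), Esrrg (0.976), Tom1l1 (1.81) and Gak (-1.27) did not pass.

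In cDC2 11 genes passed, 10 with more summits in KO and 1 with fewer. Krt8, a keratin gene, Sox17, a transcription factor gene, and Galnt18, Sh3gl3, Ogdhl and Pipox had 0 summits in both WT cDC2 libraries and 2 in both KO libraries (adjusted p between 0.024 and 0.0449). Septin1 had 2 and 4 in KO, and Has3 and Ddn 3 and 2, against 0 in WT. Fam163a had 0 and 1 in WT and 5 and 4 in KO. Iho1 fell from 2 and 2 summits to 0 in KO. With all deposited summits Septin1 (1.43), Has3 (1.27), Ddn (1.47), Ogdhl (1.06) and Iho1 (-0.725) did not pass. Over both subsets 6 genes passed. Gdpd2, Epha3, Krt8, Lypd6 and Pdzph1 rose by 1.08 to 1.33 and Gak fell by 1.08 (adjusted p = 0.0485 for each). With a pseudocount of 0.5 or autosomes alone 0 genes passed over both, and with the block 153. Values of KO and WT libraries overlapped at 4 of the 6 genes. If cDC1 and cDC2 of 1 number come from the same animal, this test rests on 2 animals per genotype.

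These genotype calls rest on 0 to 5 summits per library at each gene. With no filter on low genes 0 genes passed in cDC1, in cDC2 and over both. Among the 30868 best summits 0 of the called genes passed, but only Sh3gl3 was tested there, with a difference of 0 in cDC2. The other called genes had a mean under 1 summit in those lists and could not pass. The fit as planned called 176 genes in cDC1, 207 in cDC2 and 328 over both, of which 4, 6 and 3 were among those reported. With any 1 library left out the counts rose to between 38 and 90 in cDC1, 25 and 167 in cDC2, and 32 and 120 over both. In simulated sets without change such fits called 28 to 80 genes in cDC1 and 15 to 65 in cDC2, and none were run over both. Only replicate 1 of WT cDC1 was left out in the simulated sets, so these ranges cannot be set against fits without another library.

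Genes that define the subsets did not pass between KO and WT. The lists of cDC1 identity, cDC2 identity and DC transcription factors had 0 members past the threshold in either subset, with limma over all genes or adjusted over the list alone. Hdac1 itself (chromosome 4, 129516104 to 129542646) had 1 or 2 summits in every library, with a summit within 500 bp of a gene end in all 8. A summit count at the gene does not measure the deletion. Hdac2, the closest relative of Hdac1, and Cdkn1a, a cell cycle inhibitor, did not pass either. In the fit as planned Cdkn1a was lower in KO in cDC2 (-0.263, adjusted p = 0.000185) and over both subsets (-0.132, adjusted p = 0.000574).

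The T cell list was higher in KO as a set, while 0 of its 15 tested members passed over all genes and 1 passed adjusted over the list alone, over both subsets. In cDC2 its median log2 difference was 0.284 (adjusted p = 0.0246, and adjusted p = 0.00519 with an estimated correlation). Over both subsets it was 0.194 (adjusted p = 0.00894, and adjusted p = 0.00145 with an estimated correlation). The estimated correlation of this list was negative (-0.00794), which makes p smaller. In cDC1 the adjusted p was 0.386, and the difference between the subsets did not pass (adjusted p = 0.718). Bcl11b, a T cell transcription factor, differed by 1.04 over both subsets and Cd3e, a chain of the T cell receptor complex, by 0.54, while Cd3d and Lck differed by 0. In cDC2 the set did not pass without replicate 2 of WT (adjusted p = 0.22) or of KO (adjusted p = 0.269), without both libraries of KO number 2 (0.241), with fry (0.0943) or with a gene span with 5 kb on both sides (0.163). Over both subsets it did not pass with fry (0.254) or the gene span (0.346), and passed without both libraries of KO number 2 (0.0186). The other 17 lists did not pass in cDC1 (adjusted p between 0.27 and 0.984), in cDC2 (0.597 to 0.928) or over both (0.814 to 0.945). Against the random lists, the T cell list stood at percentiles 95.8 in cDC1, 99.7 in cDC2 and 99.8 over both. The granulocyte list stood at 99.7, 46.6 and 98.8. With fry, which works without the rounding variance, the cell cycle list was lower in KO in cDC2 (adjusted p = 0.00728) and over both (0.0457). In cDC1 the list of DC maturation and cytokines was lower in KO with the gene span (0.0381) and without replicate 1 of KO cDC1 (0.00762).

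Sites found in a single genotype were compared with other divisions of the same libraries, since 2 libraries against 2 cannot reach an exact p under 0.05. In cDC1 2560 sites were found in WT only and 2437 in KO only, 4997 together, against 3505 and 3520 for the other 2 divisions. In cDC2 2157 were found in WT only and 2614 in KO only, 4771 together, against 3746 and 3573. The balance of the sides depended on the lists. With all deposited summits 1726 sites were WT-only and 4462 KO-only in cDC1, and 1365 and 4566 in cDC2. With a score of at least 10 they were 1128 and 1650 in cDC1, and 497 and 2487 in cDC2. Such a cut follows depth, and 34782 and 36805 summits reached it in KO cDC2, against 32413 and 28226 in WT cDC2. Over both subsets 94 sites were in all 4 KO libraries and no WT library, and 78 the reverse, 172 together. This was the most among the 18 divisions with 2 libraries of each subset on a side, and the highest other left 109. The 2 that mixed WT and KO numbers alike in both subsets left 82 and 64. Such divisions are too few for a share under 0.05. Among the 10 best-ranked sites of each class in cDC1, Vkorc1l1, Maco1, Kifc2 and Camk2d had both a WT-only and a KO-only site, each 270 to 686 bp from a summit of the other genotype. In cDC2 it held, for example, for Bnip3l, Picalm and Rbl2, at 387 to 688 bp. All of the 10 best-ranked sites of each class in cDC1 and in cDC2 lay 253 to 887 bp from a summit of the other genotype. Counting sites with no summit of the other genotype within 1 kb left 1878 WT-only and 2054 KO-only sites in cDC1, and 1429 and 2082 in cDC2.

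**Figure D4:**
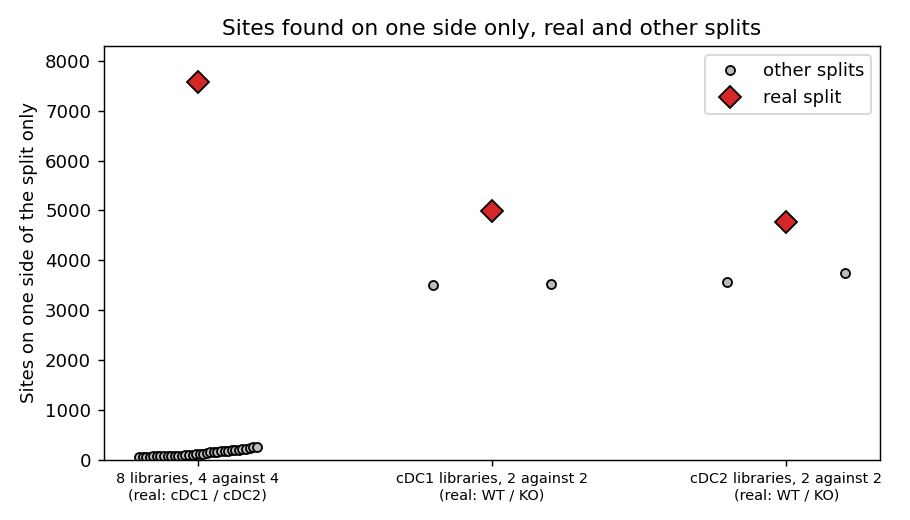
Number of sites found on a single side of a division of the libraries (vertical axis), for 8 libraries divided into 4 and 4 and for the 4 libraries of each subset divided into 2 and 2 (horizontal axis). Red diamonds are the real divisions and grey points the others. The division into cDC1 and cDC2 left 7584 sites and the highest other division 262.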

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

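Of 44 groups of 4 libraries whose highest or lowest value was compared with the others, 5 stood apart by more than the limit, where chance alone would give about 2.2. Leaving out both libraries of KO number 2, and the test of that number for the T cell genes, were chosen after these values were seen. No cause of any of the values was tested. Replicate 2 of KO cDC1 had 96031 deposited summits, and the other cDC1 libraries had between 74963 and 77585. In the equal-length lists, replicate 1 of WT cDC1 had 305 summits at DC transcription factor genes, against 290 to 292 in the other cDC1 libraries. The same library had 48 summits at interferon-stimulated genes, against 54 to 55 in the others. At erythroid and megakaryocyte genes replicate 2 of WT cDC1 had 13 summits, against 14 in each of the other cDC1 libraries. At the same genes replicate 2 of KO cDC2 had 16 summits, against 12 in each of the other cDC2 libraries.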

How the results depend on the processing

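The variance treatments, leaving out both KO number 2 libraries, the score of 10 and the 1 kb rule were chosen after the data were seen. Of the named genes 3037 values were unchanged in call under the alternatives, 317 lost and 32 gained the call, and 4 reversed. Values unchanged or kept, here and with 1 library left out, include genes called in neither fit, whose direction was not compared. With 1 library left out 1672 kept, 61 lost and 3 gained it. The causes were not tested, except that some fits were run on simulated sets without change. They called 21 to 65 genes with the block, 19 to 36 with trend and robust variance, 10 to 35 or 53 to 120 with a loess curve, 0 to 31 with rounding and trend, and 17 to 35 with the groups of a contrast alone. The 30868 best summits, the 10 kb limit, the 5 kb span and leaving out both KO number 2 libraries were not simulated. Depth is unknown and limits every statement on genes with few summits.

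Counts of genes are given in the order subset difference over both genotypes, in WT and in KO, KO minus WT in cDC1, in cDC2, the difference between these, and KO minus WT over both, leaving out those within 1.5 times. With no low filter they were 886, 128, 60, 0, 0 and 0 (no difference between these). With trend and robust variance they were 2256, 1315, 904, 124, 89, 38 and 160. With the loess average they were 2338, 1478, 820, 203, 157, 72 and 225, and with rounding and trend 2302, 1325, 925, 92, 72, 4 and 108. Raised to the loess curve, those from WT on were 828, 466, 68, 50, 14 and 69. With the block they were 922, 669, 113, 66, 38 and 153. From the subset difference in KO on, the fit as planned gave 505, 176, 207, 299 and 328, and 466, 173, 206, 300 and 322 with trend and robust. The 30868 best summits gave 480, 63, 72, 35 and 79, and the 10 kb limit 394, 39, 50, 12 and 39. All deposited summits gave 159, 1 and 22, and 10 over both. With the groups of a contrast alone they were 817, 682, 98 and 58. With a pseudocount of 0.5 they were 244 in WT, 80 in KO, 7 for cDC2 and 0 over both. The 5 kb span gave 12, 20 and 26 for KO minus WT, a mean of 3 summits 0, 2 and 1, and autosomes 0 over both. Without both KO number 2 libraries they were 847 in WT, 75, 50, 12 and 73.

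Lists past the threshold changed to 4, 5, 6 and 2 with fry (subset, WT, KO, difference of genotype effects, with cell cycle in each), to 1 in KO with an estimated correlation or the block, to 1 and 0 (subset, KO) with all deposited summits, and to 2 (WT), 1, 0 and 0 (KO minus WT) with the 5 kb span. Without both KO number 2 libraries they were 1 in KO and 0 for KO minus WT in cDC2.

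Cadm1 (0.189) and Ebf1 (0.411) reversed with the 10 kb limit, and Tnf (-0.104) and Il10 (0.0805) among the 30868 best summits. The near-end and inside differences were 0.232 and -0.743 among the 30868 best, 0.468 and -0.646 at 500 bp, and 0.882 and -0.968 with the block (p = 0.125, the smallest exact sign-flip value). With all deposited summits near-end was 2.45 (exact permutation p = 0.0571) and outside -0.636. Sites among the 30868 best were 2494 and 1666 (cDC1, cDC2 only), 1324 and 1209 (WT, KO only in cDC1) and 1121 and 1183 (in cDC2). All deposited summits gave 1714 cDC2-only, 4462 KO-only in cDC1, and 1365 and 4566 in cDC2. A score of at least 10 gave 1010 cDC2-only, 1128 WT-only in cDC1 and 497 in cDC2, and the 1 kb rule 1429 WT-only in cDC2. Jaccard indices (same group, other genotype, other subset) were 0.711, 0.692 and 0.537 among the 30868 best, 0.649, 0.634 and 0.507 with all summits, 0.618, 0.604 and 0.477 at 100 bp, and 0.704, 0.69 and 0.546 at 500 bp.

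Leaving out each library gave 1284 to 1669, 546 to 856 and 304 to 694 subset genes (both, WT, KO), 38 to 90, 25 to 167 and 32 to 120 for KO minus WT (cDC1, cDC2, both) and 1 to 38 for the difference. Lists ranged from 1 to 2, 0 to 1 and 0 to 2 (subset, WT, KO) and 0 to 1 for KO minus WT in cDC1, cDC2 and their difference. Summits per library differed by -15360 to -7273, near-end shares by 0.781 to 1.05, inside by -1.11 to -0.831 and outside by -0.00499 to 0.226. Sites were 5240 to 5893 and 3099 to 3616 (cDC1, cDC2 only), 5571 to 7505 and 4941 to 8103 (WT, KO only in cDC1), and 4486 to 8814 and 5229 to 8776 (in cDC2), where a lone library stands for its side and fewer libraries must match. Not run were motif shares (a genome sequence was not used), exons and introns (gene spans alone were used) and the best summit per peak (1 per peak).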

Other observations

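Chosen after the result was seen were all tests below except that of accessibility moving towards the other subset, that of the grouping of the animals in KO and WT, and the direct test of a genotype effect that differed between the subsets. Counts and fits repeated from the sections above keep the status given there.

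Over all 14068 genes the genotype differences of cDC1 and cDC2 correlated at 0.133, against 0.0333 and 0.012 when WT and KO libraries were mixed. Genes are not independent replicates, and libraries of both subsets may share animals.

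Of the 112443 sites 27367 (24.3%) were found in a single library and 29645 (26.4%) in all 8. Sites found in a single genotype had median ranks of score between 47174 and 48428 of 61737. The median ranks were 34135 for cDC1-only sites and 38262 for cDC2-only sites.

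The division of the libraries into cDC1 and cDC2 was compared with the other ways of dividing 8 libraries into 4 and 4. A fit with 2 group means called 1189 genes for the real division and at most 1 for any other, so 1 of the 35 divisions reached as many. Subset-only sites numbered 7584 for the real division and at most 262 for any other, again 1 of 35. This is the smallest share that 35 divisions can give, which argues against chance without excluding it. If libraries of the same number and genotype share an animal, the divisions are not interchangeable. A sign-flip test over 4 pairs could then not give a p under 0.125. For KO against WT over both subsets there are 18 divisions, too few for a share under 0.05, with 0 genes for the real division and 0 for the highest other, so that all 18 were as large in that fit. In the model with 4 group means, mixing WT and KO numbers gave 0 genes in place of 7 in cDC1, 11 in cDC2 and 6 over both, for each of the other 2 divisions, and 3 divisions are again too few.

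Fewer genes separated the subsets in KO (246) than in WT (522). The gap was smaller in the fit as planned (505 and 639) and with the groups of the contrast alone (682 and 817). It turned direction with any 1 WT library left out, where the genotypes are not compared on equal terms. A move of each subset towards the other in KO met the bounds set for it in cDC1 but not in cDC2. With subset and genotype effects taken from different libraries, the correlation across genes was 0.0509 and 0.114 in cDC1. It was -0.0086 and 0.00983 in cDC2, the lowest being -0.00983 when signed towards the other subset. These effects rest on single libraries, whose noise pulls correlations towards 0, so small values cannot decide against a move. A move of cDC1 alone stays open. The short list of WT cDC2 replicate 2 may contribute and stays open, since without it the mean Jaccard index of WT cDC1 with WT cDC2 was 0.521, against a lowest KO value of 0.526. The grouping of the animals also stays open. Only the real division of the 3 ways to pair the 4 numbers gave so uneven a ratio (1 of 3), with 267 and 226 or 253 and 270 genes in the others, and 3 ways cannot give a share under 0.05. The direct test of a genotype effect that differed between the subsets called 0 genes in the reported fit and 38 with the block. The result of 0 does not show that the effects are equal. A biological difference between the genotypes stays open.

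T cell genes had more summits in KO as a set. T cells in the KO sorts are a candidate explanation that stays open, although the sort excluded lineage-positive cells. Of the 15 tested genes 11 had more summits in KO, between the bounds of 12 and 8 set for and against it. Cd3e differed by 0.54, but Cd3d, Lck and Gata3 by 0, and each of the 15 had summits in WT libraries. KO number 2, which had the longest cDC1 list, is argued against as the only source over both subsets. The list still passed without both of its libraries (adjusted p = 0.0186), where the lone KO library of each subset was assumed to vary like the other groups, and in KO cDC1 its median difference from WT was 0.263 in replicate 1 and 0.146 in replicate 2. In cDC2 alone a part of KO number 2 cannot be told apart from a genotype effect, since the median was 0.123 in replicate 1 and 0.161 in replicate 2 and the list did not pass without that number (0.241).

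Sites found in a single genotype were more numerous than for the other divisions of the same libraries. Summits that moved within an open region are argued against as the whole cause, with ratios of 1.3 and 1.44 among sites with no summit of the other genotype within 1 kb. For the best-ranked sites moved summits stay open. Each named site found in a single genotype lay 253 to 887 bp from a summit of the other genotype. A scan of 532 windows of 5 Mb cannot decide on DNA carried along with the transgenic locus. No window passed (smallest adjusted p = 0.821, exact binomial test). The window with the smallest p held 28 sites found in a single genotype against 15.4 expected, so an excess of that size could not pass. Both genotypes carried the floxed Hdac1 gene. Summits just below the end of the equal-length lists are argued against as the whole cause in cDC1 and stay open in cDC2. Sites in the 30868 best summits of both libraries of a side, and in none of the 61737 of the other side, numbered 191 in cDC1 against at most 130 for the other divisions (ratio 1.47), a difference of 61 where the other 2 divisions lay 18 apart. In cDC2 they numbered 223 against at most 189 (ratio 1.18), a difference of 34 where the others lay 45 apart. Sites in no full list of the other side had ratios of 1.55 in cDC1 and 1.46 in cDC2. The value in cDC2 does not decide, because 92.7% and 100% of the WT cDC2 summits were already in the equal-length lists. An effect of HDAC1 loss was not tested apart from differences between the animals, and both stay open, because 3 divisions cannot give a share under 0.05. Mx1-Cre was carried by the KO mice alone, so an effect of Cre itself cannot be told apart from loss of HDAC1.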
